A study of Rattus norvegicus with 24 samples.

How the data were processed

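Liver RNA from 24 Wistar rats was sequenced: 6 males and 6 females at 110 days after birth, and 6 males and 6 females at 650 days, per the labels. Per the labels' protocols, liver of the F1 generation was homogenised in a bead beater, total RNA was extracted with miRNeasy columns, and libraries were made from 1 µg of it with the Illumina TruSeq RNA v2 kit. Reads were aligned with STAR 2.3.1j to the rat build rn5 and handled in Partek, whose version is not given in the sources used here, per the submitters' processing notes. The way reads were assigned to transcripts, the normalization and whether strand was used are not given in the sources used here.

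The deposited values are a signal per RefSeq transcript, in 1 table for females and 1 for males, each with 18572 transcripts in 12 libraries. From the values, each library's signal equals 1 plus a whole or fractional number of reads times a step of its own. The step ranged from 0.0571 to 0.127, and 83.5% to 86.8% of the values under 100 reads were whole multiples of it within 0.05 reads. Dividing each deposited total (407701 to 3687683) by its step gave 4.36 M to 39.8 M estimated reads (M, for mega) per library. The values are not whole counts, so models of whole counts were not run. The female table has 3 empty columns, and 0 columns with values were left unmatched to a sample. Of the 18572 RefSeq accessions, 17013 were found in the RefSeq gene table used for names, and 14538 had the symbol given in the file. Symbols are printed as the files give them. Some symbols stand as calendar dates in the files, and none of these is named.

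The offset of 1 was subtracted, transcripts with the same symbol were summed (996 symbols with several transcripts, 2402 transcripts, giving 17166 genes, of which 14603 were above 0 in at least 1 library), and each library was divided by a median-of-ratios size factor computed over the 10521 genes above 0 in every library (0.383 to 3.52). Values are called scaled values below. Fold changes are differences of log2(scaled value + 1), which understate the change of genes near 0. A library with 0 reads of a gene allows up to 3 reads, or 0.0789 to 0.733 scaled units depending on the library, and this limit covers counting error only. This scaling replaces the log2(value + 1) of the deposited signal that had been chosen before the data were examined, because the deposited totals differ between libraries with their depth. The unscaled values were kept as an alternative.

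Genes with a mean of at least 1 in at least 1 compared group were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method with calls at 0.05. The 5 comparisons were 650 against 110 days in the 12 females, the same in the 12 males, the difference between these age effects, and males against females at each age, the last 3 in 1 model of all 24 libraries with 4 group means. Comparisons between the sexes were to be run only if values were scaled library by library, and they were run because the step is set that way, with no rescaling of a whole table. Sex and table coincide all the same, so a difference in how the tables were made cannot be told apart from sex. The numbering of the replicates does not pair the animals by any label.

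Sets of genes were 49 lists of pathways, complexes and cell type markers, tested where at least 4 members passed the filter. The test was limma's camera with a preset correlation of 0.01, adjusted over the lists of the comparison, with camera under an estimated correlation and fry beside it. The comparisons, the test, the lists and the rule for naming genes were fixed before the data were examined. The rule names the 10 genes with the largest rise and the 10 with the largest fall among called genes with an ordinary symbol, a mean of at least 1 in the higher group and no overlap between the values of the groups compared, up to 6 of each sign for the difference between age effects without the overlap condition, and for each called list the up to 4 members with the smallest adjusted p. Names starting with LOC come from the lists only.

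The procedure was tested on simulated data in which 200 genes were changed. At a 2-fold change 83.6% were recovered for age in females, 83.6% for age in males, 80.6% for the difference between age effects, 89.2% for sex at 110 days and 86.6% for sex at 650 days. Of the calls, 4.35%, 5.88%, 6.94%, 3.61% and 5.39% were false, in the same order. All simulated libraries took the spread of the female libraries, so none was rich in muscle transcripts as 1 real male library was. With 1 list shifted as well, that list was called (adjusted p = 1.39e-21) and 0 of the other lists were. Simulated genes were drawn independently of each other, so false calls of lists whose genes move together were not tested.

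Alternatives chosen before the data were examined were quantile normalization, no variance trend, a pseudocount of 0.1, no filter and a filter at a mean of 5, centring on each library's median, the replicate number as a block, sample weights, other sets of libraries in the fit, and leaving out each library in turn. Alternatives chosen after the data were seen were the fits without the library labelled male 650 days replicate 4, the deposited values without scaling, scaling by total signal without Rn45s, transcripts in place of genes, voom on estimated reads, and the level of Rn45s, a ribosomal RNA precursor, as a covariate. Other splits of the same libraries were drawn 100 times per comparison. Reads shared between near-identical genes (the Mup, Cyp2c, Cyp3a, Sult and Ugt families among them) could be split between family members by the unstated counting, so values of single members are uncertain, as are those of overlapping genes on opposite strands.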

Results

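The livers of 24 Wistar rats were compared: 6 females and 6 males at 110 days of age, and 6 females and 6 males at 650 days, with 1 RNA library per animal. The series title concerns sexual dimorphism of the liver over the life course. The design asks how the liver transcriptome changed with age in each sex, whether these changes differed between the sexes, and how males and females differed at each age. Estimated reads per library (in M, for mega) ranged from 7.53 to 18.2 M in females of 110 days, 9.46 to 39.8 M in females of 650 days, 10.1 to 15.7 M in males of 110 days and 4.36 to 10.97 M in males of 650 days. Values per gene are scaled values, given as mean ± SD with n = 6 per group, changes are log2 fold changes ± SE, and adjusted p-values come from limma with the Benjamini-Hochberg method. The comparisons, lists of genes and naming rule were set before the data were examined, while fits without 1 male library were chosen after seeing the data. By the naming rule, genes named for the largest changes with age or sex were only those with no overlap between the groups compared.

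The sexes given by the labels were matched by genes known for sex-biased expression in rat liver. Cyp2c11, a male-specific cytochrome P450, stood at 2332 ± 175 in males and 0.592 ± 0.742 in females of 110 days, and Cyp2c12, its female-specific relative, at 7638 ± 1459 in females and 26.0 ± 14.1 in males. The Y-linked gene Ddx3y was under the expression filter in every group and told nothing about sex, and Xist, Eif2s3y and Kdm5d were not among the measured genes. The library labelled male 650 days replicate 4 stood apart. The muscle genes of the list took 10.4% of its signal, against at most 0.000667% in any of the other 23 libraries, and the muscle actin Acta1 alone took 3.93%. Albumin (Alb) took 1.19% of its signal, and its median correlation with the other libraries across genes was 0.574, against 0.933 to 0.951 for the others. Counts of genes and of lists are therefore given with and without it. The ribosomal RNA precursor Rn45s took 3.58% ± 2.60 of the signal in females of 110 days, 2.35% ± 1.60 in females of 650 days, 12.4% ± 9.53 in males of 110 days and 3.80% ± 4.12 in males of 650 days (SD, n = 6).

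**Figure D1:**
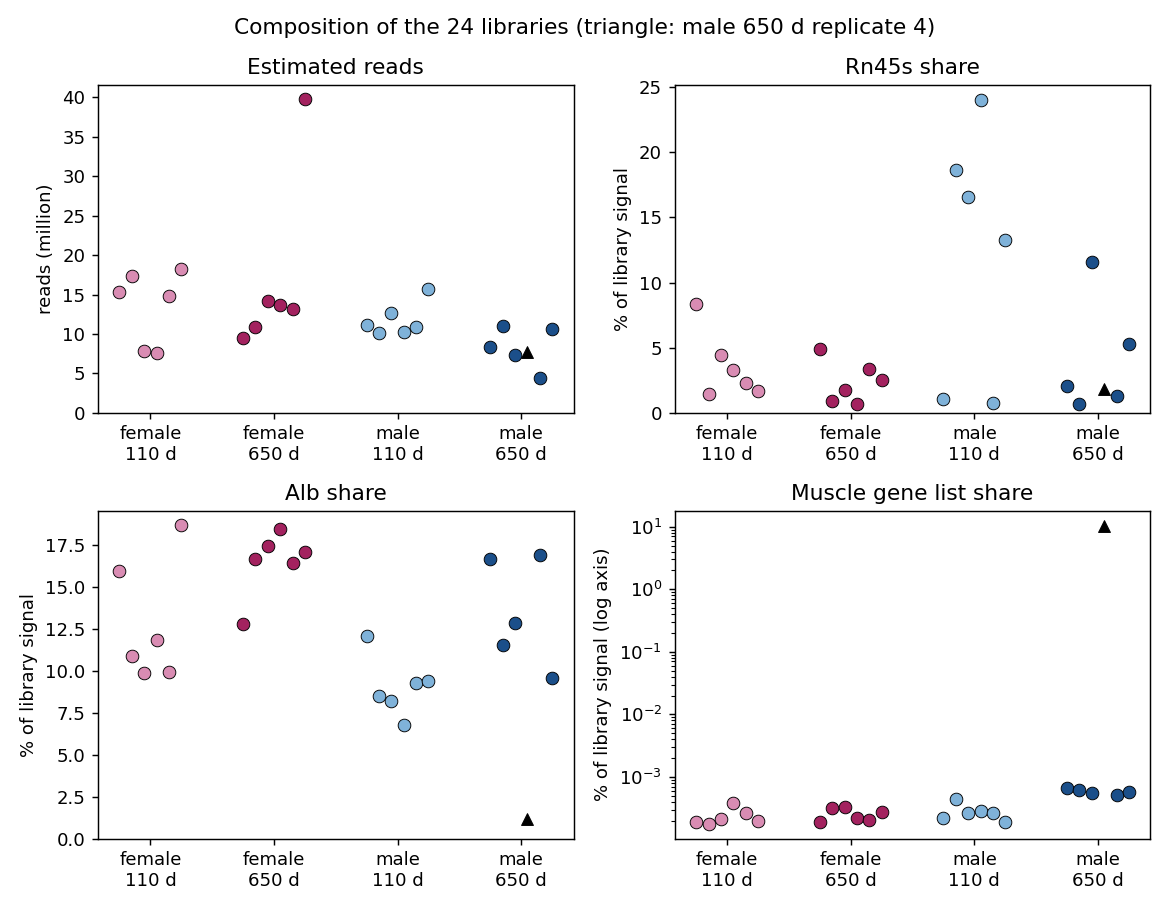
Estimated reads (M, for mega), Rn45s, Alb and muscle genes as a percentage of the deposited signal (the last on a log axis) in each library, by sex and age; points are libraries, and the triangle is male 650 days replicate 4. The triangle stands at 10.4% for muscle genes and 1.19% for Alb.

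In females, 440 of 10134 tested genes changed between 110 and 650 days, 218 up and 222 down. Rises and falls are ranked here among called genes with an ordinary symbol and no overlap between the groups. The largest such rise was that of Cox8b, the heart and muscle form of a cytochrome c oxidase subunit, from 0.0525 ± 0.0746 to 10.7 ± 3.81 (3.41 ± 0.19, adjusted p = 8.01e-07). Ear11, of the eosinophil-associated ribonuclease family, rose from 0.0937 to 9.10 (3.06 ± 0.28, adjusted p = 7.13e-05), and Cdh17, the liver-intestine cadherin, from 1.05 to 13.5 (2.87 ± 0.40). Hsd11b1, which regenerates active glucocorticoid, rose from 14.4 ± 5.84 to 71.2 ± 24.4 (2.22 ± 0.28, adjusted p = 0.00145). Other large rises were those of Lrtm2 (2.53 ± 0.32), the sodium-calcium exchanger Slc24a3 (2.26 ± 0.46) and the potassium channel Kcnn2 (2.26 ± 0.17). Lppr3 (2.23 ± 0.49), the adhesion molecule Nfasc (2.18 ± 0.23) and Ptk7 (1.94 ± 0.31) rose as well. The largest falls without such overlap were those of Rnf186 (-1.59 ± 0.31) and the acyl-CoA thioesterase Acot5 (-1.39 ± 0.29). The cytochrome P450 Cyp3a23/3a1 fell from 535 ± 264 to 203 ± 67.3 (-1.33 ± 0.32), and its relative Cyp3a18 fell too (-1.31 ± 0.26). Akap5 (-1.31 ± 0.22), the fatty acid-binding protein Fabp7 (-1.31 ± 0.21) and Cela1 (-1.28 ± 0.26) fell. Obp3 of the alpha-2u globulin family fell from 2.90 ± 1.76 to 0.511 ± 0.310 (-1.28 ± 0.25). Rtn4rl1 (-1.25 ± 0.23) and Csrp2 (-1.15 ± 0.13) also fell. A library of a young female with 0 reads of a gene allows a level of up to 0.174 to 0.396. The means at 110 days of Cox8b and Ear11 lay under this range and those of Kcnn2 (0.225), Nfasc (0.297) and Lppr3 (0.392) within it, so these fold changes depend on the 1 added before taking logs. Of the 440 genes, 43 rose and 25 fell at least 2-fold. Igf1, the insulin-like growth factor made by the liver and a reference gene, fell from 289 ± 24.8 to 191 ± 25.9 (-0.60 ± 0.10, adjusted p = 0.00617). The count was 63 on the deposited values without depth scaling, 51 up and 12 down. Leaving out 1 library lowered it to 235, 227 or 215 (110 days replicates 2, 3 and 5), or to 275, 279, 229 or 292 (650 days replicates 2, 3, 5 and 6).

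Among the 44 lists tested in females, 16 were called, none of them with an estimated correlation between genes. Of 18 genes of stellate cells and myofibroblasts, 6 rose (7 adjusted over the list alone), among them Cygb (0.98 ± 0.14), Ecm1 (0.74 ± 0.12), Lhx2 (0.83 ± 0.13) and Reln (0.80 ± 0.15). The stellate cell list had a camera adjusted p of 4.40e-06 (adjusted p = 0.478 with an estimated correlation), and by fry its adjusted p was 0.0299. Extracellular matrix genes gave 3 of 35 up (4 adjusted over the list alone), with Bgn (0.68 ± 0.12), Pdgfra (0.59 ± 0.11) and Col4a1 (0.40 ± 0.09). The matrix list had a camera adjusted p of 0.000639 (adjusted p = 0.478 with an estimated correlation). Macrophage genes had 3 of 25 up (4 adjusted over the list alone), namely Gpnmb (1.41 ± 0.32), Cd68 (0.54 ± 0.13) and the scavenger receptor Marco (0.93 ± 0.22). The macrophage list had a camera adjusted p of 1.83e-06 (adjusted p = 0.478 with an estimated correlation). Of 24 endothelial genes, 4 rose (4 adjusted over the list alone), namely Eng (0.45 ± 0.09), Dnase1l3 (0.38 ± 0.08), Egfl7 (0.49 ± 0.11) and Lyve1 (0.39 ± 0.09). The endothelial list had a camera adjusted p of 0.00587 (adjusted p = 0.59 with an estimated correlation). Interferon response genes had a median of 0.42 with 2 of 34 up (11 adjusted over the list alone), Oasl (1.41 ± 0.21) and Oasl2 (1.05 ± 0.23). The interferon list had a camera adjusted p of 2.44e-07 (adjusted p = 0.478 with an estimated correlation). Ribosomal protein genes had a median of 0.15 with 5 of 75 up (10 adjusted over the list alone), among them Rpl12 (0.34 ± 0.05), Rpl37a (0.45 ± 0.10) and Rps6 (0.29 ± 0.07). The ribosomal protein list had a camera adjusted p of 1.81e-14 (adjusted p = 0.478 with an estimated correlation). Acute phase genes had 1 of 27 up (4 adjusted over the list alone), Lcn2 (1.82 ± 0.43). The acute phase list had a camera adjusted p of 0.00299 (adjusted p = 0.489 with an estimated correlation). Of the 4 neutrophil genes S100a9 (1.35 ± 0.26) rose (2 adjusted over the list alone). The neutrophil list had a camera adjusted p of 0.0108 (adjusted p = 0.478 with an estimated correlation). Senescence genes had 2 of 31 up (3 adjusted over the list alone), Gpnmb and Bhlhe40 (0.64 ± 0.16). The senescence list had a camera adjusted p of 0.0158 (adjusted p = 0.478 with an estimated correlation). The counts of members depended on the scaling: with total-signal scaling 1 ribosomal protein gene, 1 endothelial and 1 macrophage gene rose, and with quantile normalization 8 ribosomal protein and 4 interferon response genes. With the Rn45s covariate 0 acute phase genes passed.

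Other called lists were lower at 650 than at 110 days in females, several of them of liver metabolism. Of 39 genes of fatty acid oxidation and other PPARA targets, 4 fell and 1 rose (17 down and 1 up, adjusted over the list alone), with a median of -0.44. Bdh1 (-0.60 ± 0.10), Eci2 (-0.56 ± 0.10) and Decr1 (-0.51 ± 0.12) fell and Cyp4a8 (1.47 ± 0.26) rose. The fatty acid oxidation list had a camera adjusted p of 6.65e-10 (adjusted p = 0.478 with an estimated correlation). Of 42 genes of phase I drug metabolism, 8 fell (12 down and 1 up, adjusted over the list alone), including Aox1 (-0.47 ± 0.08), Cyp2d2 (-0.53 ± 0.10) and Cyp4f1 (-0.52 ± 0.11). The phase I list had a camera adjusted p of 3.46e-07 (adjusted p = 0.478 with an estimated correlation). Heat shock genes had 4 of 15 down (9 adjusted over the list alone), namely Hspb1 (-1.58 ± 0.30), Hspe1 (-0.49 ± 0.11), Hsp90aa1 (-0.93 ± 0.20) and Hsp90ab1 (-0.56 ± 0.14). The heat shock list had a camera adjusted p of 8.56e-07 (adjusted p = 0.478 with an estimated correlation). Bile acid genes had 3 of 25 down (5 down and 1 up, adjusted over the list alone), the sterol exporters Abcg8 (-1.93 ± 0.34) and Abcg5 (-1.52 ± 0.39) and the conjugate exporter Abcc2 (-0.62 ± 0.14). The bile acid list had a camera adjusted p of 0.00954 (adjusted p = 0.478 with an estimated correlation). The proteasome list had 1 of 31 down (5 adjusted over the list alone), Psmc6 (-0.38 ± 0.09). The proteasome list had a camera adjusted p of 3.49e-08 (adjusted p = 0.478 with an estimated correlation). Its median of -0.18 turned to 0.04 without depth scaling. Of 19 genes known to be male-biased in liver, 3 fell (6 adjusted over the list alone), Obp3, Cyp3a18 and Mup5 (-1.81 ± 0.42). In females Obp3 went from 2.90 to 0.511 and Mup5 from 6.11 to 0.820, against 8674 and 13336 in males of 110 days. At such low levels the changes depend on the 1 added before taking logs, and the source of these reads was not tested. The male-biased list had a camera adjusted p of 0.0156 (adjusted p = 0.478 with an estimated correlation). Of 21 female-biased genes, 2 fell (5 adjusted over the list alone), Adh4 (-0.62 ± 0.16) and Trim24 (-0.58 ± 0.15). The female-biased list had a camera adjusted p of 0.033 (adjusted p = 0.478 with an estimated correlation). With total-signal scaling 2 heat shock and 0 proteasome genes fell, and with quantile normalization 2 heat shock and 0 female-biased genes. More fell in other settings: 5 male-biased genes with quantile normalization or the Rn45s covariate, 3 proteasome genes with median centring and 2 with that covariate.

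In males, 61 of 10791 tested genes changed with age in all 12 libraries, 33 up and 28 down, and 1260 of 10190, 566 up and 694 down, without the library labelled male 650 days replicate 4. All 61 were among the 1260. Rises and falls are again ranked among called genes with an ordinary symbol and no overlap between the groups. Igfbp2, which binds insulin-like growth factors, rose most, from 1.83 ± 1.88 to 49.9 ± 25.9 (4.22 ± 0.35, adjusted p = 0.000318). Tpd52l1 (2.69 ± 0.41), the forkhead factor Foxq1 (2.14 ± 0.29), Rhbdl3 (2.09 ± 0.22) and the phospholipase Pla1a (1.99 ± 0.35) rose. So did the cation channel Trpm4 (1.80 ± 0.31), Arl4d (1.38 ± 0.25), Banp (1.17 ± 0.19), Disp1 (1.10 ± 0.21) and the dynein adaptor Bicd2 (1.08 ± 0.21). The largest falls were those of the methyltransferase Inmt (-3.73 ± 0.69) and of the carboxylesterase Ces1f (-2.52 ± 0.43), from 323 ± 71.7 to 66.5 ± 42.5. Pex11a, which acts in peroxisome proliferation, came next (-2.25 ± 0.43). Eci1, an enoyl-CoA isomerase of fatty acid oxidation, fell from 406 ± 153 to 94.8 ± 43.7 (-2.11 ± 0.28, adjusted p = 0.0162). Then came Cyp2d4 (-1.95 ± 0.27), the progestin receptor Paqr7 (-1.66 ± 0.29), Mocs2 (-1.16 ± 0.22) and Enpep (-1.09 ± 0.19). Cpt2, a carnitine palmitoyltransferase, fell from 162 ± 24.0 to 76.8 ± 9.57 (-1.07 ± 0.13, adjusted p = 0.00771), and Trim2 fell as well (-0.96 ± 0.15). Igf1 stood at 349.8 ± 111 and 205 ± 93.2 (-1.02 ± 0.51, adjusted p = 0.326) in males. Without male 650 days replicate 4 the mean of Igf1 in old males was 240.3 ± 35.9 and the change -0.49 ± 0.20, adjusted p = 0.119. The difference of its age effect from that in females turned from -0.42 ± 0.54 to 0.11 ± 0.23 without it, and passed in neither fit. Leaving out 1 library gave 29, 4, 3, 4 and 4 genes for 110 days replicates 1, 3, 4, 5 and 6. It gave 8, 15, 152, 3 and 13 for 650 days replicates 1, 2, 3, 5 and 6. The balance of rises and falls depended on the scaling, with 10 up and 353 down without depth scaling and 58 up and 24 down with total-signal scaling. The count was 363 and 82 in these fits, 23 with quantile normalization, 24 with voom, 35 without a variance trend, 33 without a filter and 2 with the Rn45s level as a covariate. Rn45s had taken 12.4% of the signal at 110 days and 3.80% at 650 days.

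In the 12 male libraries 20 of 45 lists were called, none with an estimated correlation. Of 39 genes of fatty acid oxidation and PPARA targets, 6 fell (21 down and 1 up, adjusted over the list alone), including Cpt2, Eci1, Pex11a and the carnitine carrier Slc25a20 (-0.87 ± 0.14). The list had a median of -0.76 and a camera adjusted p of 2.23e-15 (adjusted p = 0.436 with an estimated correlation). Of 24 male-biased genes 0 passed over all genes and 12 were lower adjusted over the list alone. Their median was -1.57, with a camera adjusted p of 2.92e-10 (adjusted p = 0.436 with an estimated correlation). Klf6 (0.99 ± 0.17) was the 1 of 19 immediate early genes to rise (5 adjusted over the list alone). The immediate early list had a camera adjusted p of 0.00125 (adjusted p = 0.15 with an estimated correlation). Ets2 (0.98 ± 0.15) was the 1 of 31 senescence genes to rise (2 adjusted over the list alone). The senescence list had a camera adjusted p of 0.0141 (adjusted p = 0.436 with an estimated correlation), and its median of 0.26 turned to -0.29 without depth scaling. The muscle genes had a median of 1.99 with 0 of 13 passing (0 adjusted over the list alone) and a camera adjusted p of 0.0204 (adjusted p = 0.766 with an estimated correlation). The hepatocyte genes had a median of -0.56 with 0 of 25 passing. For the hepatocyte list there was a camera adjusted p of 0.0206 (adjusted p = 0.81 with an estimated correlation). Both lists move with the library that is rich in muscle transcripts, without which the hepatocyte median was 0.01.

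Without that library, 11 male libraries were left (6 of 110 and 5 of 650 days). Igfbp2 rose by 4.32 ± 0.35, to 53.3 ± 27.3. The fatty acid synthase Fasn rose from 103 ± 81.0 to 488 ± 141 (2.46 ± 0.39, adjusted p = 0.00381). Lcn2, an acute phase protein, rose from 2.09 ± 1.77 to 20.8 ± 16.2 (2.61 ± 0.47, adjusted p = 0.00563). Rgs16 (2.97 ± 0.61), the chemokine Cxcl1 (2.79 ± 0.47), and the organic anion transporter Slc21a4 (2.75 ± 0.33) were among the 10 largest rises with no overlap between the groups. The immediate early factor Egr1 (2.55 ± 0.48), Unc5cl (2.40 ± 0.33), Foxq1 (2.37 ± 0.20) and Tpd52l1 (2.33 ± 0.27) were the others. Sult1e1, the estrogen sulfotransferase, fell from 1275 ± 393 to 392 ± 171 (-1.77 ± 0.29, adjusted p = 0.00389). The other large falls with no overlap between the groups were those of Inmt (-3.82 ± 0.70), Stac3 (-2.96 ± 0.55), Colq (-2.22 ± 0.44) and Tor3a (-2.22 ± 0.35). Ces1f (-2.15 ± 0.27), Cyp2b2 (-2.09 ± 0.35), Eci1 (-2.02 ± 0.27), Pex11a (-2.02 ± 0.38) and the transporter Slc22a8 (-1.81 ± 0.31) followed. From this count of 1260, leaving out 1 more library gave 753 (110 days replicate 3), 821, 791 or 716 (650 days replicates 1, 2 and 5), and the Rn45s covariate gave 695. The balance of rises and falls depended on the scaling here too, with 108 up and 1986 down without depth scaling (2094 genes) and 729 up and 384 down with total-signal scaling (1113 genes).

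Among 43 lists in these 11 libraries, 23 were called, again none with an estimated correlation. Fatty acid oxidation and PPARA targets fell, with 24 of 39 down and 1 up (29 down and 1 up, adjusted over the list alone), including Cpt2 (-1.02 ± 0.11) and Acadl (-0.77 ± 0.12). Here the fatty acid oxidation list had a camera adjusted p of 4.42e-13 (adjusted p = 0.162 with an estimated correlation). Oxidative phosphorylation genes had 20 of 68 down (38 adjusted over the list alone) with a median of -0.25, such as Uqcrfs1 (-0.34 ± 0.07) and Ndufb3 (-0.48 ± 0.10). Here the oxidative phosphorylation list had a camera adjusted p of 1.92e-14 (adjusted p = 0.42 with an estimated correlation). Of 24 male-biased genes 16 fell (18 down and 1 up, adjusted over the list alone), with a median of -1.03, including Cyp2c11 (-1.07 ± 0.17), Dhrs7 (-1.66 ± 0.28), Obp3 (-2.40 ± 0.42) and Sult1e1. Here the male-biased list had a camera adjusted p of 1.72e-09 (adjusted p = 0.162 with an estimated correlation). Of 43 phase I genes 17 fell and 3 rose (25 down and 4 up, adjusted over the list alone), with falls of Cyp2d4 (-1.75 ± 0.21) and Cyp2d3 (-0.61 ± 0.10). Here the phase I list had a camera adjusted p of 1.78e-06 (adjusted p = 0.12 with an estimated correlation). Pericentral genes had 4 of 17 down (8 adjusted over the list alone), among them Lect2 (-1.05 ± 0.17), Cyp1a2 (-1.13 ± 0.19) and the xenobiotic receptor Nr1i3 (-1.23 ± 0.35). Here the pericentral list had a camera adjusted p of 0.00018 (adjusted p = 0.384 with an estimated correlation). Of 25 cholesterol synthesis genes, with a median of 0.89, 10 rose (16 adjusted over the list alone), including Acat2 (1.26 ± 0.20), Mvk (0.93 ± 0.18) and Fdps (1.30 ± 0.28). Here the cholesterol synthesis list had a camera adjusted p of 2.37e-09 (adjusted p = 0.42 with an estimated correlation). Lipogenesis had 8 of 26 up and 2 down (11 up and 2 down, adjusted over the list alone), with Fasn, Acly (1.82 ± 0.29) and Thrsp (1.23 ± 0.24) up. Here the lipogenesis list had a camera adjusted p of 0.00813 (adjusted p = 0.42 with an estimated correlation). Acute phase genes had 11 of 27 up (15 adjusted over the list alone), among them Stat3 (1.31 ± 0.17), Il1rn (0.84 ± 0.16) and Cp (0.64 ± 0.12). Here the acute phase list had a camera adjusted p of 4.44e-07 (adjusted p = 0.12 with an estimated correlation). Immediate early genes had 5 of 18 up (10 up and 1 down, adjusted over the list alone), such as Junb (1.56 ± 0.26) and Btg2 (0.86 ± 0.15). Here the immediate early list had a camera adjusted p of 0.00104 (adjusted p = 0.12 with an estimated correlation). Of 15 bile duct genes 5 rose (7 adjusted over the list alone), with Elf3 (1.35 ± 0.21), Epcam (1.39 ± 0.28) and Krt19 (0.80 ± 0.20). Here the bile duct list had a camera adjusted p of 9.41e-05 (adjusted p = 0.162 with an estimated correlation). The fetal and preneoplastic list had 5 of 17 up (9 adjusted over the list alone), with H19 (1.65 ± 0.22) and Spink3 (1.25 ± 0.22). Here the fetal and preneoplastic list had a camera adjusted p of 0.000349 (adjusted p = 0.0995 with an estimated correlation). Senescence genes had 6 of 31 up and 1 down (7 up and 1 down, adjusted over the list alone), with Ets2 (1.03 ± 0.14), Mapk14 (0.40 ± 0.08) and Cdkn1c (0.85 ± 0.21) up. Here the senescence list had a camera adjusted p of 0.0263 (adjusted p = 0.42 with an estimated correlation). The counts of members depended on the setting. With total-signal scaling 13 oxidative phosphorylation genes fell, and with the Rn45s covariate 6. With that covariate 6 acute phase, 2 bile duct and 2 fetal and preneoplastic genes rose. By fry, which asks whether a list's genes move one way on balance, the adjusted p was 0.00276 for fatty acid oxidation, 0.00245 for male-biased genes and 0.000725 for the acute phase.

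**Figure D2:**
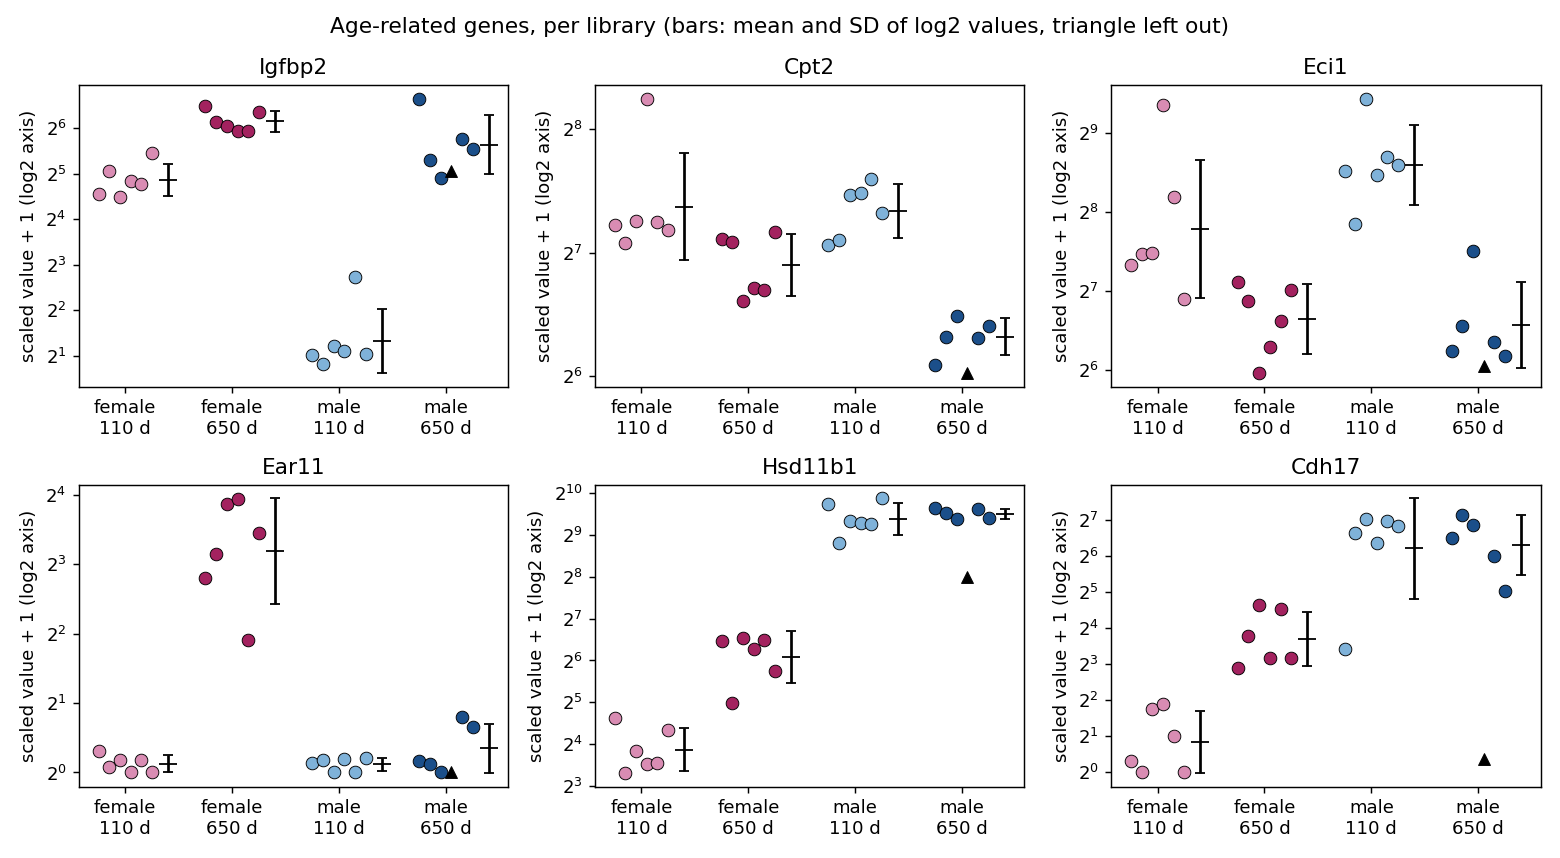
Scaled value + 1 on a log2 axis of Igfbp2, Cpt2, Eci1, Ear11, Hsd11b1 and Cdh17 in each library by sex and age; points are libraries, bars the mean and SD of log2 values, and the triangle is male 650 days replicate 4, left out of the bars. Igfbp2 rose by 4.22 in males (12 libraries) on the log2 scale, and Ear11 by 3.06 in females.

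**Figure D3:**
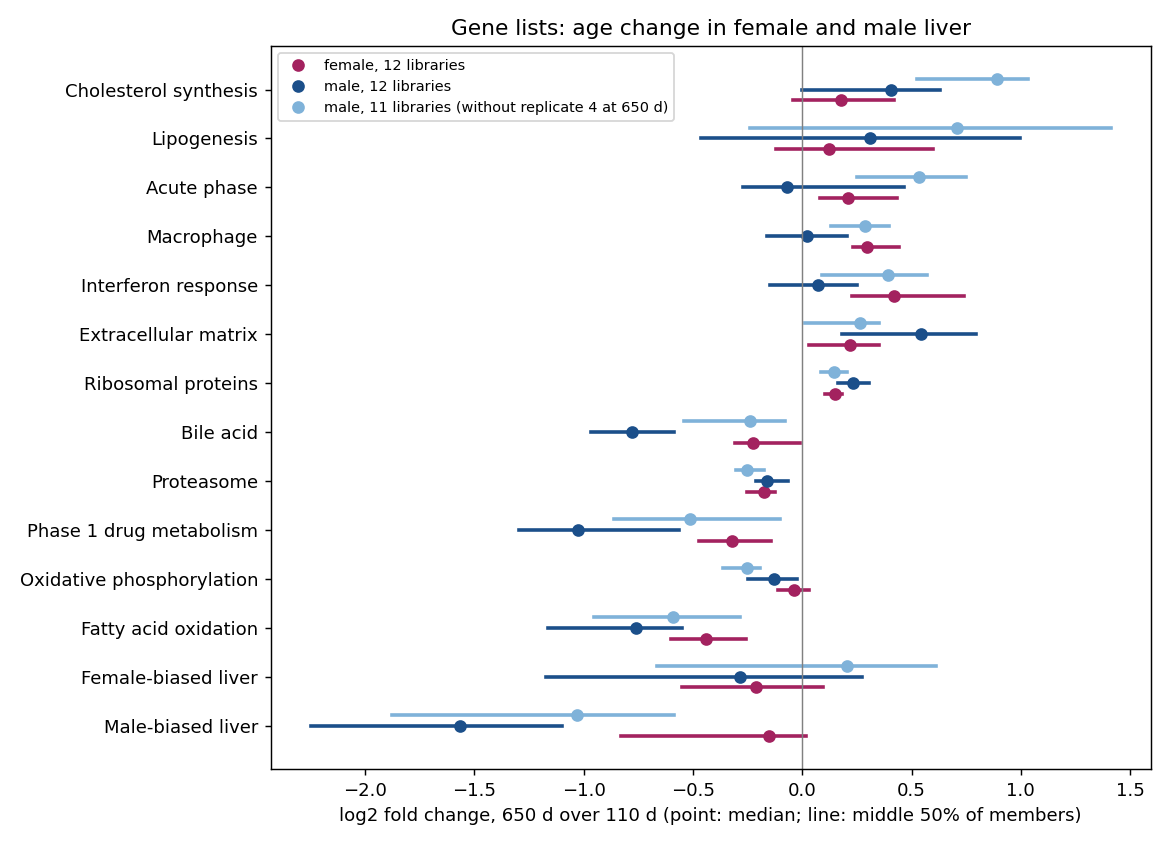
Log2 fold change of 650 against 110 days for 14 lists of genes: points are list medians and lines the middle 50% of members, for females (12 libraries), males (12 libraries) and males without male 650 days replicate 4 (11 libraries). The median of fatty acid oxidation was -0.44, -0.76 and -0.59, in that order, and called medians that turn sign are the proteasome (0.04 in females without depth scaling, 0.01 in the 12 males with total-signal scaling) and, in the 12 males, ribosomal proteins (-0.33 without depth scaling) and oxidative phosphorylation (0.04 with total-signal scaling).

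The age changes of the sexes overlapped. With all libraries 6 genes rose in both sexes (0.690 expected from the margins) and 4 fell in both (0.594 expected). Of the genes tested in both, 0 were called in opposite directions. Without the library rich in muscle transcripts 60 rose (11.4 expected) and 77 fell (15.0 expected) in both, and 2 that fell in females rose in males. Across genes, which are not independent replicates, the log2 fold changes of the sexes correlated with r = 0.380, and r = 0.410 without that library.

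The difference between the age effects (males minus females) passed for 13 of 10932 genes, 7 up and 6 down, and for 115 of 10390, 61 up and 54 down, without the library labelled male 650 days replicate 4. Igfbp2 differed by 2.93 ± 0.40, adjusted p = 0.000996: its level went from 1.83 ± 1.88 to 49.9 ± 25.9 in males and from 28.9 ± 7.93 to 71.0 ± 11.8 in females. Hsd11b1 differed by -2.34 ± 0.42, adjusted p = 0.0221, with 688 ± 179.8 and 653 ± 202 in males (732 without that library) against 14.4 and 71.2 in females. Ear11 differed by -2.89 ± 0.35, adjusted p = 0.000267. Rhbdl3 (1.85 ± 0.36), the prolyl hydroxylase P4ha1 (1.33 ± 0.27), Ppp2r1b (1.32 ± 0.23), Bicd2 (1.15 ± 0.22) and the survival factor Mcl1 (0.80 ± 0.15) had the more positive effect in males. The lymphocyte receptor Lag3 (-1.37 ± 0.26), Ssbp1 (-0.88 ± 0.18) and Zfp386 (-0.69 ± 0.13) had it in females. Without that library, Slc21a4 (2.75 ± 0.35), listed at 0 in every female library, Foxq1 (1.99 ± 0.35), Pla1a (1.97 ± 0.35) and Nupr1 (1.74 ± 0.38) joined the 6 largest on the male side. Stac3 (-5.48 ± 1.30), Cox8b (-3.34 ± 0.23), listed at 0 in every young male, Inmt (-3.24 ± 0.76), Lrtm2 (-2.43 ± 0.59) and Slc24a3 (-2.27 ± 0.53) joined those on the female side. Of 47 lists 20 were called (12 of 45 without that library), none of them in either fit with an estimated correlation or by fry, and in the fit of all libraries 1 of their members passed by itself, Hsd11b1 in the list of steroid receptors and metabolism (4 adjusted over the list alone). Between the age effects the steroid list had a camera adjusted p of 0.000535 (adjusted p = 0.754 with an estimated correlation). The male-biased list had a median difference of -1.20 with 0 of 24 passing (6 lower in males adjusted over the list alone). Between the age effects the male-biased list had a camera adjusted p of 9.96e-08 (adjusted p = 0.754 with an estimated correlation). Without that library it was -0.73, with lower effects in males for Sult1e1 (-1.67 ± 0.31), Mup4 (-1.78 ± 0.40) and Stac3 (9 down and 1 up, adjusted over the list alone). In females of 110 and 650 days Sult1e1 averaged 0.134 and 0.0599, and Mup4 0.153 and 0.0151. With 1 added before taking logs, genes so near 0 in females can hardly fall there. For such members of the list the difference therefore mostly gives the male change. In that fit the male-biased list had a camera adjusted p of 0.000104 (adjusted p = 0.597 with an estimated correlation). The oxidative phosphorylation list, with a median of -0.24 in that fit and 1 of 68 lower in males (1 adjusted over the list alone), Ndufb3 (-0.50 ± 0.12), had a camera adjusted p of 3.81e-11 (adjusted p = 0.597 with an estimated correlation). Leaving out 1 library gave 5, 8, 5 and 6 genes for females of 110 days replicates 2, 3, 4 and 6. It gave 6, 5, 8 and 5 for females of 650 days replicates 2, 3, 4 and 5. For males the values were 29, 6 and 6 for 110 days replicates 2, 3 and 4, and 42 and 8 for 650 days replicates 3 and 5. From 115 it gave 183 and 347 without males of 110 days replicates 1 and 2, and 274 without male 650 days replicate 3. It gave 41 to 76 without females of 110 days replicates 2, 5 or 6, females of 650 days replicates 2, 3 or 6, males of 110 days replicates 3, 4, 5 or 6, or males of 650 days replicates 1 or 5. Under other scalings the 115 became 112 genes, 5 up and 107 down, without depth scaling, and 178 genes, 135 up and 43 down, with total-signal scaling. Another split of those libraries, of 100 drawn, called 417 genes.

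At 110 days 1230 of 10101 genes differed between the sexes, 582 higher in males and 648 higher in females, with all 24 libraries in the model. The count was 2664 (1303 and 1361) without the library labelled male 650 days replicate 4. The differences themselves are the same with and without it, and the counts differ through the spread shared by all groups. Male-specific genes stood high in males against levels near 0 in females. The level of Cyp2c11 was 2332 ± 175 against 0.592 ± 0.742 (10.62 ± 0.42, adjusted p = 4.09e-15), and that of Obp3 8674 ± 3449.8 against 2.90 ± 1.76 (11.11 ± 0.44, adjusted p = 4.66e-15). Mup5 (11.11 ± 0.51), Cyp2c13 (10.12 ± 0.43), Sult1e1 (10.09 ± 0.36), the steroid dehydrogenase Hsd3b5 (9.48 ± 0.38) and ste2 (9.46 ± 0.34) were also higher in males. So were Cyp3a2 (8.43 ± 0.49), Mup4 (8.38 ± 0.39) and Slc22a8 (8.17 ± 0.36). The plasma protein A1bg stood at 5619.8 ± 2060.2 in females and 0.441 ± 0.586 in males (-11.93 ± 0.26, adjusted p = 6.86e-20), and Cyp2c12 differed by -8.27 ± 0.46, adjusted p = 1.97e-12. The reductase Akr1b7 (-9.21 ± 0.43), the transcription factor Cux2 (-5.57 ± 0.40) and the sulfotransferase Sult2a2 (-6.75 ± 0.89) were higher in females. So were the carboxypeptidase Cpa1 (-6.02 ± 0.59) and the receptors Lifr (-5.41 ± 0.30) and Prlr (-5.22 ± 0.59), with Prlr at 935 ± 284 against 34.6 ± 31.6. Where a sex stood near 0, the log2 difference depends on the 1 added before taking logs. Reads of the Mup, Cyp2c, Cyp3a and Sult families can be shared between near-identical members, so single members are less certain than families. The share of Rn45s differed between these groups, at 3.58% in females and 12.4% in males. The count was 311 without depth scaling (124 higher in males), 1063 with total-signal scaling (372 higher in males) and 2251 with the 12 libraries of 110 days alone.

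Of the 42 lists tested at 110 days 15 were called, and the male-biased and female-biased lists were also called with an estimated correlation. Without the library labelled male 650 days replicate 4 there were 16 of 42, and the lysosome list was also called with an estimated correlation (adjusted p = 0.00924). Of 24 male-biased genes 18 were higher in males (20 adjusted over the list alone), with a median of 6.19. The male-biased list had a camera adjusted p of 2.15e-41 (adjusted p = 0.0126 with an estimated correlation). Of 21 female-biased genes 15 were higher in females (16 adjusted over the list alone), with a median of -2.48, including Trim24 (-4.71 ± 0.26). The female-biased list had a camera adjusted p of 8.06e-20 (adjusted p = 0.0163 with an estimated correlation). Lipogenesis genes had 6 of 26 higher in females (10 in females and 1 in males, adjusted over the list alone), with the fatty acid transporter Cd36 (-4.33 ± 0.30), Elovl6 (-1.90 ± 0.34), Acaca (-1.30 ± 0.33) and Scd (-2.15 ± 0.55). The lipogenesis list had a camera adjusted p of 6.77e-05 (adjusted p = 0.813 with an estimated correlation). Cholesterol synthesis had 3 of 25 higher in females (6 adjusted over the list alone), Fdps (-1.90 ± 0.43), Tm7sf2 (-1.66 ± 0.41) and Mvd (-1.33 ± 0.40). The cholesterol synthesis list had a camera adjusted p of 7.44e-06 (adjusted p = 0.904 with an estimated correlation). Lysosome and autophagy genes had 5 of 30 higher in females (6 adjusted over the list alone), including Ctsd (-0.65 ± 0.08) and Ulk1 (-0.70 ± 0.11). The lysosome list had a camera adjusted p of 0.001 (adjusted p = 0.813 with an estimated correlation). Endothelial genes had 3 of 24 higher in females (4 adjusted over the list alone), Flt4 (-0.90 ± 0.23), Cdh5 (-0.95 ± 0.26) and Flt1 (-0.80 ± 0.24). The endothelial list had a camera adjusted p of 0.00239 (adjusted p = 0.813 with an estimated correlation). In the growth hormone and IGF axis, 6 of 19 genes were higher in females and 1 in males (6 in females and 1 in males, adjusted over the list alone), with Igfbp2 (-3.54 ± 0.28), Onecut1 (-1.56 ± 0.31), Igfbp1 (-2.80 ± 0.62) and Prlr on the female side. The growth hormone axis list had a camera adjusted p of 0.0243 (adjusted p = 0.813 with an estimated correlation). Steroid receptors and metabolism went both ways, with 6 of 20 higher in males, such as Hsd11b1 (5.52 ± 0.30) and Nr1i3 (2.65 ± 0.45), and 2 in females, among them Srd5a1 (-3.14 ± 0.51). The counts adjusted over the list alone were 6 and 2. The steroid list had a camera adjusted p of 0.0243 (adjusted p = 0.995 with an estimated correlation). Of 40 genes of fatty acid oxidation and PPARA targets 6 were higher in males (6 in males and 1 in females, adjusted over the list alone), including Cyp4a2 (3.96 ± 0.44), Cyp4a8 (4.47 ± 0.61) and Hadh (0.68 ± 0.19). The fatty acid oxidation list had a camera adjusted p of 0.0256 (adjusted p = 0.995 with an estimated correlation). More members passed without the library labelled male 650 days replicate 4, while their differences stayed the same. In that fit 20 of 25 cholesterol synthesis genes, 12 of 26 lipogenesis genes, 14 of 30 lysosome and autophagy genes and 9 of 24 endothelial genes were higher in females. Lipogenesis and the lysosome list had 1 each higher in males. There were 8 in females and 2 in males for the growth hormone axis, 9 in males and 3 in females for steroids, and 9 in males and 1 in females for fatty acid oxidation. The male-biased list had 20 and the female-biased list 16.

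**Figure D4:**
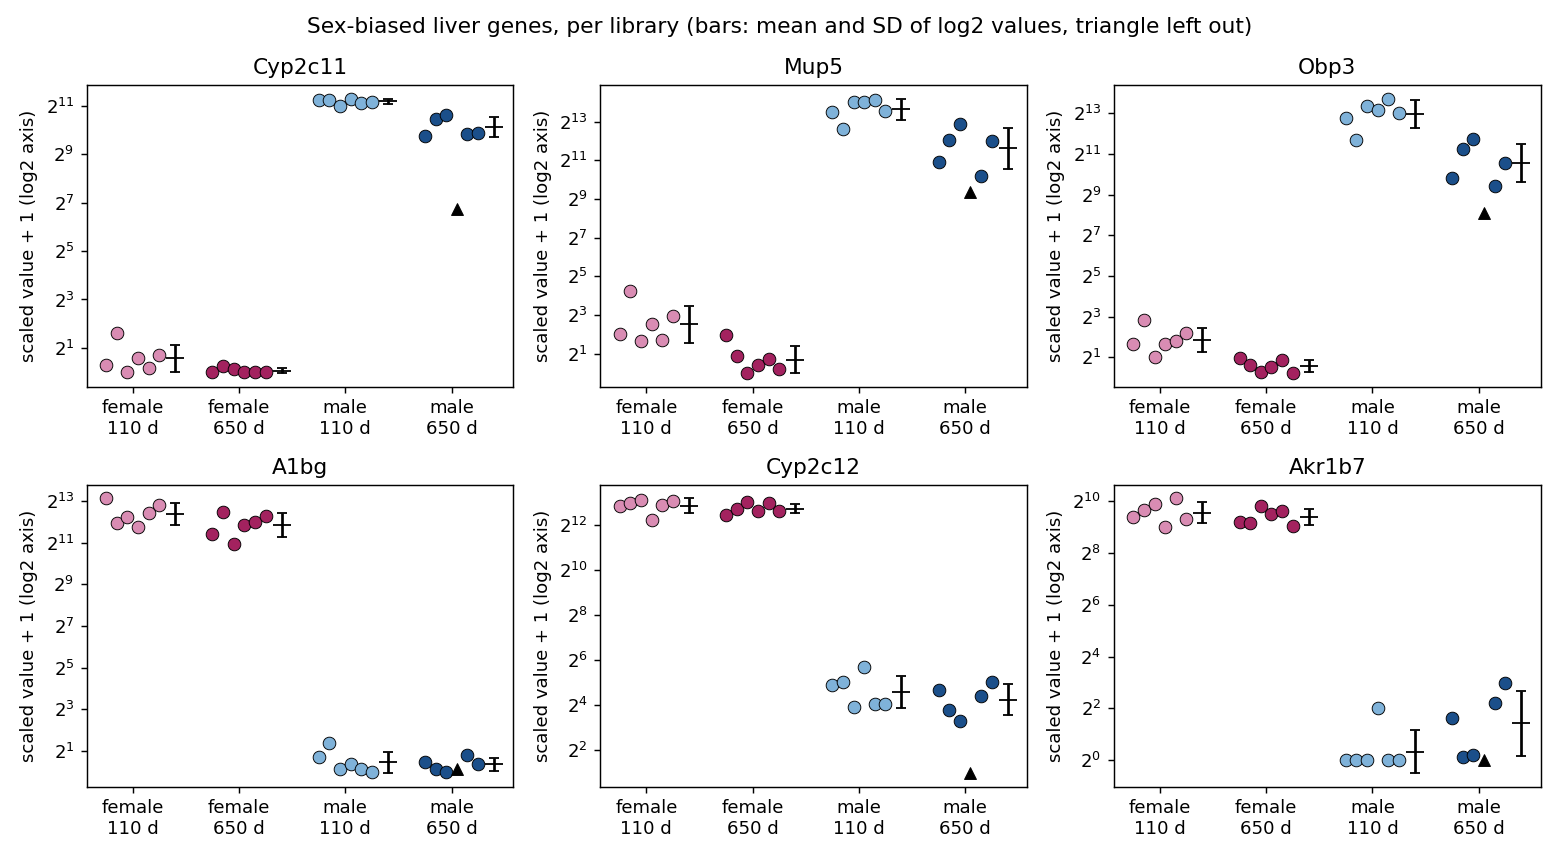
Scaled value + 1 on a log2 axis of Cyp2c11, Mup5, Obp3, A1bg, Cyp2c12 and Akr1b7 in each library by sex and age; points are libraries, bars the mean and SD of log2 values, and the triangle is male 650 days replicate 4, left out of the bars. At 110 days Cyp2c11 averaged 2332 in males and 0.592 in females, and A1bg 5619.8 in females and 0.441 in males.

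At 650 days 1216 of 10860 genes differed between the sexes, 538 higher in males and 678 in females, and 2009 of 10299 (1014 and 995) without the library labelled male 650 days replicate 4. Cyp2c11 stood at 971 ± 519 in males (1144 without that library) and 0.0454 ± 0.0786 in females (9.49 ± 0.42, adjusted p = 5.12e-14). A1bg stood at 3863 ± 1387 in females and 0.261 ± 0.269 in males (-11.52 ± 0.27, adjusted p = 1.83e-19). Mup5 (10.53 ± 0.51), Obp3 (9.58 ± 0.44), Cyp2c13 (9.45 ± 0.43), Hsd3b5 (8.68 ± 0.38), Sult1e1 (7.97 ± 0.36) and ste2 (7.81 ± 0.34) were higher in males, as were Cyp3a2 (7.34 ± 0.49), the acyltransferase Acnat2 (6.93 ± 0.44) and Mup4 (6.18 ± 0.39). Without that library the difference was 10.05 ± 0.20 for Cyp2c11, 10.03 ± 0.20 for Cyp2c13, 7.95 ± 0.30 for Cyp3a2 and 7.53 ± 0.19 for Acnat2. Cyp2c12 (-9.04 ± 0.46), Sult2a2 (-8.98 ± 0.89) and Akr1b7 (-8.18 ± 0.43) were higher in females, as were Cpa1 (-6.25 ± 0.59), Lifr (-5.34 ± 0.30) and Cux2 (-5.32 ± 0.40). The count was 5893, with 97 higher in males, on the deposited values without depth scaling, which shifts the median of all genes by -0.74. With total-signal scaling it was 1134, 695 higher in males and 439 in females. It was 587 with the 12 libraries of 650 days alone.

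Of 47 lists at 650 days 17 were called, and the male-biased, female-biased and pancreas lists were also called with an estimated correlation. Without the library labelled male 650 days replicate 4 there were 16 of 45. Of 24 male-biased genes 16 were higher in males (17 adjusted over the list alone), with a median of 4.90 (5.51 without that library). The male-biased list had a camera adjusted p of 3.78e-28 (adjusted p = 0.0283 with an estimated correlation). Of 21 female-biased genes 15 were higher in females (15 adjusted over the list alone), with a median of -3.38 (-2.75 without that library). The female-biased list had a camera adjusted p of 4.97e-22 (adjusted p = 0.0217 with an estimated correlation). Of the 4 pancreas genes 3 were higher in females, including Cpa1 and Amy2a3 (-0.77 ± 0.24), and Cela1 (1.76 ± 0.35) in males (3 and 1 adjusted over the list alone). The pancreas list had a camera adjusted p of 0.000829 (adjusted p = 0.0259 with an estimated correlation). Without the library rich in muscle transcripts that p was 0.113. Lists of immune cell markers were called as higher in females. T and NK cell genes had 7 of 16 higher (14 adjusted over the list alone), including Il2rb (-1.22 ± 0.19), Zap70 (-1.14 ± 0.26) and Cd7 (-0.80 ± 0.19). The T and NK cell list had a camera adjusted p of 2.20e-07 (adjusted p = 0.282 with an estimated correlation). Macrophage genes had 3 of 25 higher (19 adjusted over the list alone), Gpnmb (-1.02 ± 0.30), Fcgr1a (-0.79 ± 0.25) and Vsig4 (-1.11 ± 0.36). The macrophage list had a camera adjusted p of 2.20e-07 (adjusted p = 0.672 with an estimated correlation). Interferon response genes had 5 of 34 higher in females (8 adjusted over the list alone), such as Ifi47 (-3.67 ± 0.33) and Oasl2 (-1.14 ± 0.28). The interferon list had a camera adjusted p of 5.78e-07 (adjusted p = 0.711 with an estimated correlation). Pericentral genes had 7 of 16 higher in females (11 in females and 1 in males, adjusted over the list alone), with Cyp1a2 (-1.83 ± 0.31), Lect2 (-1.99 ± 0.35), the glutamine synthetase Glul (-1.19 ± 0.22) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-3.01 ± 0.58). The pericentral list had a camera adjusted p of 3.09e-05 (adjusted p = 0.163 with an estimated correlation). Lipogenesis had 7 of 26 higher in females (8 adjusted over the list alone), with Cd36 (-3.04 ± 0.30), Scd (-4.04 ± 0.55) and Dgat2 (-1.61 ± 0.26). The lipogenesis list had a camera adjusted p of 1.63e-05 (adjusted p = 0.672 with an estimated correlation). Cholesterol synthesis had 2 of 25 higher in females (5 adjusted over the list alone). The cholesterol synthesis list had a camera adjusted p of 5.65e-05 (adjusted p = 0.799 with an estimated correlation). It was not called without the library rich in muscle transcripts (camera adjusted p = 0.0709). Immediate early genes had 3 of 19 higher in males (4 adjusted over the list alone), Btg2 (0.94 ± 0.17), Ier2 (0.87 ± 0.20) and Egr1 (2.12 ± 0.57). The immediate early list had a camera adjusted p of 0.00957 (adjusted p = 0.282 with an estimated correlation). Its median of 0.44 turned to -0.22 without depth scaling. Without the library rich in muscle transcripts it was 0.11 (camera adjusted p = 0.0432). In that fit 5 immediate early genes were higher in males. Higher in females were 6 T and NK cell genes (9 adjusted over the list alone), 3 macrophage genes (2 adjusted over the list alone), 3 cholesterol synthesis genes and 15 female-biased genes. The interferon list had 6 higher in females and 1 in males, the pericentral list 9 and 2, and lipogenesis 7 and 1. The male-biased list had 18 higher in males. The immune lists leaned toward females at 110 days too, without the library rich in muscle transcripts. Macrophage genes had a median of -0.42 at both ages, with 7 higher in females at 110 days. Interferon response genes had -0.22 at 110 days (5 higher in females, 1 in males) and -0.25 at 650 days. T and NK cell genes had -0.18 at 110 days (2 higher in females) and -0.51 at 650 days.

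The sex differences of the ages overlapped. Of the genes tested at both ages 212 were higher in males at both (28.8 expected from the margins) and 286 higher in females at both (42.4 expected), and 2 higher in males at 110 days were higher in females at 650 days. Without the library rich in muscle transcripts the counts were 516 (124 expected) and 538 (130.3 expected), with 6 higher in males at 110 days and in females at 650 days, and 9 the other way round. Across genes, which are not independent replicates, r was 0.798, and 0.854 without that library. Cdkn1a, a cell cycle inhibitor and reference gene, was higher in males at 110 days, at 24.6 ± 15.2 against 5.03 ± 5.94 (2.27 ± 0.45, adjusted p = 0.00121), and at 650 days, at 48.6 ± 17.5 against 8.49 ± 3.07 (2.38 ± 0.45, adjusted p = 0.000935). Its age effect did not pass in females (1.01 ± 0.43, adjusted p = 0.189) or males (1.13 ± 0.40, adjusted p = 0.173), and Cdkn2a was under the expression filter in every group.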

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

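The tests on the muscle transcripts and their traces, and the fits without the library labelled male 650 days replicate 4, were chosen only after the result was seen; the random splits were planned. The libraries were split at random into groups of the same sizes, 100 splits with the real one included. The real one alone reached its own count in 8 of the fits. That share of 1 in 100 argues against chance for the comparisons of age and of sex. Splits for the difference between age effects shuffled ages within each sex, which also removed the age effects themselves. They therefore cannot decide chance for that difference. The real count and the highest of the other splits were 440 and 2 for age in females, 61 and 2 for age in males (1260 and 7 without the library labelled male 650 days replicate 4) and 13 and 1 for the difference between age effects. They were 1230 and 290 for sex at 110 days (2664 and 1124 without it) and 1216 and 7 for sex at 650 days (2009 and 991 without it), and splits that mix the sexes can call genes in these. For the difference between age effects without that library 2 of the 100 splits reached the real count of 115, with 417 in the other. The make-up of that other split was not examined, so what gave its 417 genes is not known. Chance is not excluded for the count of 115, which should not be read as age and sex alone.

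The age effect differed between the sexes by a test of the difference for 13 genes and 20 lists (115 genes and 12 lists without that library), and with an estimated correlation or by fry for 0 lists in either fit. Among the named genes the difference, males minus females on the log2 scale, was 2.93 for Igfbp2, 1.85 for Rhbdl3, 1.33 for P4ha1, 1.32 for Ppp2r1b, 1.15 for Bicd2 and 0.80 for Mcl1. It was -2.89 for Ear11, -2.34 for Hsd11b1, -1.37 for Lag3, -0.88 for Ssbp1 and -0.69 for Zfp386. Without that library it was also 2.75 for Slc21a4, 1.99 for Foxq1, 1.97 for Pla1a and 1.74 for Nupr1, and -5.48 for Stac3, -3.34 for Cox8b, -3.24 for Inmt, -2.43 for Lrtm2 and -2.27 for Slc24a3.

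In 25 of 237 groups of libraries the highest or lowest library stood far from the others of its group, with its gap to the nearest given as a fraction of the group's range; chance gives about 1 in 20, or 11.8 of these groups. Among males of 110 days, replicate 5 was high for Igfbp2 (0.802) and Lcn2 (0.634) and low for Nupr1 (0.686), and replicate 2 was low for Lrtm2 (0.71). Among males of 650 days, replicate 3 was high for Eci1 (0.652, and 0.714 without replicate 4), replicate 5 low for Ssbp1 (0.724) and replicate 6 high for Cux2 (0.766, and 0.854 without replicate 4). Among females, 110 days replicate 4 was low for Cyp2c12 (0.697) and 650 days replicate 3 high for Sult2a2 (0.791). Female 650 days replicate 6 was high in estimated reads (0.845) and in genes above 0 (0.715), and replicate 1 low in the shares of Alb (0.636) and of hepatocyte genes (0.687).

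Male 650 days replicate 4 was high in muscle genes (1.00), low in hepatocyte genes (0.644) and in its correlation with the other libraries (0.976), low for Hsd11b1 (0.838), Cyp2c11 (0.772), Cyp2c13 (0.71), Hsd3b5 (0.669), ste2 (0.629) and Acnat2 (0.89), and high for Cpa1 (0.899). A small share of muscle RNA in a liver library is argued against, since the median of 25 hepatocyte genes was 8.62% of their mean in the other 5 old males (5.31% to 13.0%). Mostly muscle RNA with a small share of male liver RNA is a candidate explanation: Acta1 stood at 27171, Ckm at 10409 and Mb at 7395, while Cyp2c11 was 52.9 times and Cyp2c13 83.2 times the highest female library, at 9.39% and 8.49% of the other old males. A swap of labels with another male library of the series could not be decided. The muscle share was at most 0.000667% in the other 23 libraries, but a swap would leave 1 muscle-rich library all the same. Whether the muscle came in at dissection, at extraction or from another sample stays open, and no biological explanation was tested.

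The other 5 males of 650 days had slight traces of the same muscle genes, at a median of 0.00407% of the level in replicate 4. Of the 13 genes, 12 were higher on average than in males of 110 days. Casq1 averaged 3.22 against 2.48, and the other means in these old males were only 0 to 0.693. In these males a library with 0 reads of a gene allows up to 0.261 to 0.733. Apart from Casq1 the means lay within or under that range, which is a limit for 1 library and not for a mean. Acta1 was above 0 in each of these 5 libraries, at 4.10e-05% to 0.000103% of the signal. Among males of 110 days only replicate 5 held it, at 9.16e-06%. Gaps ran from wide (Acta1, 0.693 against 0.0154) to slight (Actn3, 0.137 against 0.119), and counting error was not tested for them. Reads of replicate 4 carried over into the others could give such traces. Over the 13 genes the mean level in the others rose with the level in replicate 4 (Spearman rho = 0.516 across genes, which are not independent replicates). A little muscle tissue in each old male cannot be told apart from such carry-over. The rho of 0.516 was the one test, and no other muscle was measured. Age stays open as an untested explanation.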

How the results depend on the processing

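Fits without the library rich in muscle transcripts (male 650 days replicate 4), without depth scaling, with total-signal scaling, on transcripts, with voom and with the Rn45s covariate were chosen after seeing the data; the others were planned. Methods for whole counts had been planned and were not run, because the values are not whole counts; voom was run on estimated reads. Counts moved by over 1.5 times as follows, and the cause was not tested unless given. For age in females (440) the count was 143 with the replicate number as a block, 804 with sample weights, 63 without depth scaling, 235 with total-signal scaling and 43 with all 24 libraries in 1 model, which shares the spread with the library rich in muscle transcripts. For age in males (61) it was 23 with quantile normalization, 35 without a variance trend, 33 without a filter, 7 with the block, 1864 with sample weights, 363 without depth scaling, 24 with voom, 2 with Rn45s, 1176 with all 24 libraries and 1260 without the library rich in muscle transcripts. For the difference between age effects (13) it was 8 with quantile normalization, 4 with the block, 449 with weights, 5 without depth scaling, 3 with voom, 7 with Rn45s and 115 without that library. For sex at 110 days (1230) it was 3016 with weights, 311 without depth scaling, 2251 with 1 age in the fit and 2664 without that library. For sex at 650 days (1216) it was 2192, 5893, 587 and 2009, in the same order. No label pairs animals by replicate number. Same-number correlations between groups ran from -0.230 to 0.151, and such weak values cannot exclude a pairing.

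Without the library rich in muscle transcripts, the 1260 genes for age in males became 717 with the block, 2094 without depth scaling, 695 with Rn45s and 2002 with all other libraries in 1 model. The 115 for the difference became 72 without a filter, 59 with the block, 415 with sample weights, 178 with total-signal scaling and 67 with Rn45s. The 2664 for sex at 110 days became 495, and the 2009 for sex at 650 days 5935, without depth scaling. The balance of rises and falls also turns with the scaling in these fits.

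Leaving out each library in turn gave 215 to 590, 3 to 1260, 5 to 115, 994 to 2664 and 904 to 2009 genes, in the same order of comparisons. The lists called fell from 16, 20, 20, 15 and 17 to 0, 0, 0, 2 and 3 with an estimated correlation and 1, 1, 0, 5 and 9 with fry, and for the difference between age effects to 12 without the library rich in muscle transcripts. With the block they were 16, 21, 22, 15 and 17.

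Of the values of named genes under the alternatives, 1706 of 2070 kept direction and side of the threshold for age in females, 3437 of 4116 for age in males, 4821 of 5074 for the difference between age effects, 3204 of 3508 for sex at 110 days and 3968 of 4278 for sex at 650 days. Cp with age in males turned to 0.64 with sample weights and to 0.64 without the library rich in muscle transcripts, with -0.21 to 0.64 when each library was left out. Proc at 650 days turned to 0.29 and 0.30 in the same fits, with -0.38 to 0.30 when each library was left out, and Ier2 at 650 days turned to -0.012 without depth scaling. Without depth scaling the median of all genes shifted by 0.18, -0.44, -0.62, -0.11 and -0.74 in the 5 comparisons, and total-signal scaling shifted it by 0.18 for age in males, 0.20 for the difference and 0.16 for sex at 650 days, so directions of small changes depend on the scaling.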

Other observations

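The tests of the male-biased list were chosen before its result under them was seen, except that with family sums, while the fits without male 650 days replicate 4 and with the Rn45s covariate were added only after the data were seen. In the 11 male libraries without it, more lists moved with age. Of 34 interferon response genes 7 rose (10 adjusted over the list alone), including Ifih1 (0.57) and Irf7 (1.13). Here the interferon list had a camera adjusted p of 3.83e-05 (adjusted p = 0.42 with an estimated correlation). Extracellular matrix genes had 5 of 38 up (7 adjusted over the list alone), with Thbs2 (0.90), Col4a1 (0.59) and Vim (0.55). Here the matrix list had a camera adjusted p of 0.00171 (adjusted p = 0.42 with an estimated correlation). Lists of cell type markers moved in the same fit, and not all one way. Macrophage genes had 1 of 25 up, Cd163 (1.06; 1 adjusted over the list alone). Here the macrophage list had a camera adjusted p of 0.0121 (adjusted p = 0.762 with an estimated correlation). Endothelial genes had 1 of 24 up, Esam (0.51; 0 adjusted over the list alone). Here the endothelial list had a camera adjusted p of 0.0413 (adjusted p = 0.794 with an estimated correlation). T and NK cell genes had 2 of 14 down, Cd7 (-0.58) and Il2rb (-0.53), with 5 adjusted over the list alone. Here the T and NK cell list had a camera adjusted p of 0.00813 (adjusted p = 0.426 with an estimated correlation). With the Rn45s covariate 3 interferon, 2 matrix and 0 T and NK cell genes passed in these directions, and with total-signal scaling 0 T and NK cell genes. More passed with quantile normalization, at 8 interferon, 7 matrix and 5 T and NK cell genes, and 3 T and NK cell genes fell with median centring. The interferon and matrix changes were therefore not separated from a change in the cells present. Proteasome genes had 8 of 31 down (16 adjusted over the list alone), such as Psmc3 (-0.32) and Psmc6 (-0.48). Here the proteasome list had a camera adjusted p of 3.42e-07 (adjusted p = 0.42 with an estimated correlation). With total-signal scaling 0 proteasome genes fell, and with quantile normalization or the Rn45s covariate 2. Bile acid genes had 8 of 25 down (9 down and 1 up, adjusted over the list alone), including the uptake carrier Slc10a1 (-0.63) and Amacr (-1.02). Here the bile acid list had a camera adjusted p of 0.00266 (adjusted p = 0.42 with an estimated correlation), and 4 fell with the Rn45s covariate. In the list of steroid receptors and metabolism 6 of 20 fell and 1 rose (10 down and 3 up, adjusted over the list alone), with Sult2a1 (-1.76) and Hsd17b10 (-0.37) down. Here the steroid list had a camera adjusted p of 0.0239 (adjusted p = 0.162 with an estimated correlation), and 3 fell with total-signal scaling. The urea cycle and amino acid list was called downward with a median of -0.29, while its 1 passing member of 28 (1 adjusted over the list alone), the glycine decarboxylase Gldc, rose (1.04). Here the urea cycle list had a camera adjusted p of 0.0263 (adjusted p = 0.762 with an estimated correlation).

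Male-biased genes were lower in old than in young males, with a median log2 fold change of -1.03 over 24 genes and 16 of them falling, without male 650 days replicate 4. Ribosomal RNA content as the whole cause is argued against: with the log2 Rn45s level as a covariate the median was -1.02, and 14 fell. A lower share of hepatocytes is argued against, since the median of 25 hepatocyte genes was 0.00876 (middle of the list from -0.08 to 0.27). Lower depth of the old male libraries, acting on genes near 0, is argued against. The 21 members with a mean of at least 100 in young males had a median of -1.07. They are most of the same 24 genes, and choosing them by the young male level leans toward a fall. Female-biased genes did not move one way in the same fit: of 19, 1 rose and 4 fell (4 down and 1 up, adjusted over the list alone), with a median of 0.21 and a camera adjusted p of 0.905 (adjusted p = 0.961 with an estimated correlation). Reads moving between members of a gene family are argued against as the whole cause. Each gene was replaced by the sum of its family. Of 15 families or genes without one, 13 were lower, with a median of -0.813 (middle of these from -1.61 to -0.40). That median is the value of Rgn, and genes without a family cannot test a move of reads within one. The sums of several genes were all lower, from -1.98 for the alpha-2u globulins to -0.27 for Cyp2a and -0.19 for Slco1a. Single members stay uncertain. A change with age is then a hypothesis, found and tested on the same data, and hormones were not measured. A difference in how samples of young and old males were handled was not tested and cannot be told apart from age.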
